A study of Mus musculus with 2 samples.

How the data were processed

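Liver RNA was purified with a column kit, copied into double-stranded cDNA and transcribed in vitro into biotin-labelled RNA, per the labels' protocols, and hybridised to Affymetrix mouse arrays. There was 1 array from a control mouse and 1 from a Tmprss6-deficient mouse, grouped by their titles. The deposited values are intensity signals, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. The values themselves show a linear scale, from 0 to 42541, and the same mean signal on both arrays once the lowest and highest 2% of probe sets are left out, so the arrays look already scaled to a common value. MAS5 summarises each array alone, and its signals near background are noisy. Detection calls and scanner images were not used here, so a floor on the signal stands in for detection, and saturation could not be assessed.

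Probe sets were named through the platform annotation. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and were left unnamed, and 9211 were not listed in the table used here. For 34754, the gene identifier was found in the RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used only for names and for which genes neighbour each other, since no genome build is given for the array values, and no coordinates are printed.

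The arrays were scaled to the same trimmed mean, signals below the floor were set to it, and log2 was taken. The floor of 17.8 is the median over both arrays of all probe sets other than the 64 controls. A gene is represented by its probe set with the highest mean log2 signal, and ratios are Tmprss6-deficient over control. Of 18193 named genes, 10243 were above the floor on both arrays and 12243 on at least 1, and the 5950 below it on both got no ratio. A gene above the floor on 1 array has only a bound, written "at least" and taken against the floor. A gene is called measured in a list where above the floor on at least 1 array, and a probe set where above it on both. Probe sets are said to be in disagreement where measured sets of a gene have ratios of opposite sign. Over 19894 probe sets above the floor on both arrays, the log2 signals of the 2 arrays correlated with r = 0.969, across probe sets, which are not independent replicates. Near-identical genes, such as Hamp and Hamp2, the Saa genes and members of the Cyp2c, Cyp4a, Mup and Ugt2b families, can hybridise to each other's probes, and their values are uncertain for that reason.

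No test and no p-value can be given with 1 array per group. The spread between probe sets of the same gene is the SD of the difference in log2 ratio between the 2 brightest measured sets of a gene, divided by the square root of 2. It was 0.37 over 4367 genes and is given by signal range in the text. The median log2 ratio of each of 36 gene lists was set against 10000 random lists of the same size, with each member drawn from the 200 genes nearest in mean signal. Members were counted as higher or lower at 1.5-fold or more. A list is said to stand apart below percentile 2.5 or above 97.5, which describes these 2 arrays and is not a test of the genotype. Lists with fewer than 5 measured genes got no percentile, genes with a bound entered at that bound, and 73 of 656 list entries had no probe set naming that gene alone.

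The lists, floor, thresholds, alternatives and the rule for named genes were fixed before the data were examined. Named genes are Tmprss6, Hamp and Hamp2, the 15 largest ratios in each direction among genes with a mean signal of 76.7 (the 75th percentile) or more whose measured probe sets shared a direction, the 5 largest bounds in each direction among genes whose brighter signal reached that level, and up to 4 members of each list with the largest ratios, with further members of the BMP-SMAD, iron and acute-phase lists. Hpn, Ifit1, Alb, Ttr, Klf1, Krt19 and Cldn7 lie outside this rule and were chosen after their values were seen, as were Tfrc, Tfr2, Slc40a1, Fth1, Mt1 and Hp among the list members and the contractile and epithelial genes of the closing observations.

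The procedure was tested on arrays simulated from the control array with probe-level noise, in which 200 bright genes among 18193 were changed. Of 50 genes changed by each size, 10.0% of those changed 1.5-fold, 58.0% of those changed 2-fold, 100% of those changed 3-fold and 96.0% of those changed 4-fold passed 2-fold in the right direction. Of 200 unshifted lists of 20 genes, 9 stood apart, and 94 of 100 lists shifted by 0.3 on the log2 scale were called higher. This simulation leaves out variation between animals and has no genes that vary together. Its unshifted lists were random draws, so their share called is not an error rate for the gene lists used here. The alternatives were scaling to the median, no scaling, quantile normalization and loess, floors at the 30th and 70th percentile, the floor as a pseudocount, the mean of all probe sets, plain probe sets only (identifiers without a letter for shared or similar probes), thresholds of 1.5-fold and 3-fold, random lists not matched on signal, and lists of genes above the floor on both arrays only. Lists without some of their members were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.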

Results

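Gene expression was measured on Affymetrix whole-genome mouse arrays in the livers of 2 male mice aged 3 months, of mixed 129Sv and C57BL6 background, after a fast overnight. The control group held 1 animal and the Tmprss6-deficient group held 1 animal. Tmprss6 encodes matriptase-2, a membrane-bound serine protease of the hepatocyte that restrains production of the iron hormone hepcidin. The comparison asks how the liver transcriptome differs between an animal that lacks the protease and a control. Each array carried 45101 probe sets. Leaving out 64 control sets, 22272 on the control array and 22773 on the other had a signal at or above the floor of 17.8. With 1 array per genotype there is no replicate error and no test, and each difference below is a difference between these 2 animals. The number of arrays limits the precision. The only error the data give is the spread of the log2 ratio between probe sets of the same gene, which leaves out the variation between animals. Its SD was 0.44 for signals from the floor to 64, 0.35 from 64 to 256, 0.26 from 256 to 1024 and 0.16 above 1024.

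The targeted gene was read by probe set 1428676_at. Tmprss6 had a signal of 1868 in the control liver and 88.1 in the Tmprss6-deficient liver, where it was 21.2-fold lower, in the direction that the sample labels give. Whether these probes lie in the deleted part of the gene is not given in the sources used here. Among type II transmembrane serine proteases and their partners, Tmprss2 was 2.81-fold higher on the brightest of 3 measured probe sets, all of them higher, while Hpn, which encodes the liver protease hepsin, read 2528 and 2687 in control and Tmprss6-deficient liver. The log2 ratio was 0.48 for Hgf, with its probe sets in disagreement and a set above the floor only in the control at least 1.03-fold lower, 0.16 for Hgfac and -0.26 for Prss8. The median log2 ratio of this list was 0.088 over 9 measured genes, with 1 higher and 1 lower by 1.5-fold or more, within the range of random lists of like signal. Genes near Tmprss6 on its chromosome had a median of -0.016 over 23 genes, also within that range, with 1 higher and 5 lower by 1.5-fold or more. Of these, Lgals1 (galectin-1) was 4.25-fold lower on the brighter of its 2 probe sets and 2.22-fold lower on the other. Sh3bp1 was 1.61-fold lower and Gga1 1.74-fold higher. Ift27 was 2.04-fold lower on its brightest probe set, with the other measured set in the opposite direction. A set of Ift27 above the floor only in the control was at least 2.40-fold lower.

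Most genes differed little between the 2 livers. Of 10243 genes above the floor on both arrays, 84.1% lay within 1.5-fold, and the median log2 ratio was -0.0098. At 2-fold or more, 204 genes were higher and 247 were lower in the Tmprss6-deficient liver. A further 87 genes were above the floor only in the Tmprss6-deficient liver, and 93 only in the control, by at least 2-fold over the floor. Where a gene 2-fold higher had a second measured probe set, that set pointed the same way for 47 of 59 genes, and for 56 of 73 genes 2-fold lower, against 60.8% of all 4367 genes with a second measured set. With both probe sets at a mean signal of 76.7 or more, the direction was shared by 21 of 22 higher and 24 of 24 lower genes. Fewer second sets also passed 2-fold in that direction, 22 of the 59 for higher and 21 of the 73 for lower genes. With both sets at that signal, 11 of the 22 and 15 of the 24 did. In arrays simulated with probe-level noise, 67 of the genes left unchanged passed 2-fold. That noise was normal, with the same SD for all probe sets within a signal range, and left out variation between animals. So 67 does not estimate how many of the observed 2-fold differences are noise.

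**Figure D1:**
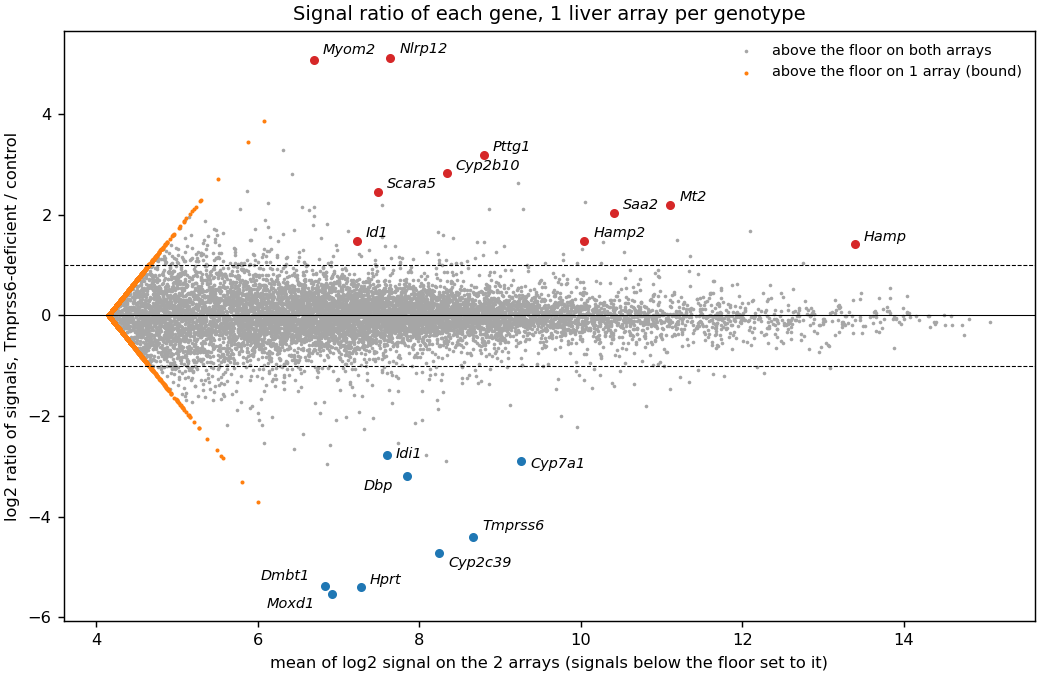
Log2 ratio of signals (Tmprss6-deficient over control, y axis) against the mean log2 signal of both arrays (x axis), with 1 point per gene, 1 array per genotype and dashed lines at 2-fold. Grey genes were above the floor on both arrays and orange genes on 1 array only. Named genes are red where higher and blue where lower. Moxd1, Dmbt1 and Myom2 are at their bounds, with Moxd1 lowest at -5.54. The other named genes run from Hprt at -5.41 and Tmprss6 at -4.41 to Hamp at 1.41 and Nlrp12 at 5.11.

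Hepcidin and genes that respond to bone morphogenetic protein (BMP) signalling through SMAD factors were higher in the Tmprss6-deficient liver. Hamp, which encodes hepcidin, the hormone that blocks iron release into plasma, read 6593 and 17531 on probe set 1419196_at and 5207 and 15241 on 1419197_x_at in control and Tmprss6-deficient liver. It was 2.66-fold and 2.93-fold higher, or 1.41 and 1.55 on the log2 scale, against a probe set spread of 0.16 at that signal. Its close paralog Hamp2 was 2.79-fold higher, and since the genes are near-identical, these probe sets may not tell them apart. Of 10 measured BMP-SMAD targets, 9 were higher and 1 was lower by 1.5-fold or more, and the median log2 ratio of 1.22 lay above all 10000 random lists of like signal. Id1, an inhibitor of differentiation, read 89.7 and 249.8 and was 2.78-fold higher. Id2 was 2.75-fold higher on its brightest probe set, 2.97-fold on another and 1.08-fold on a dim set, and Id3 was 2.19-fold higher. The transcription factor Atoh8 was 2.48-fold higher, and the feedback inhibitors Smad6 and Smad7 were 1.86-fold and 1.53-fold higher. Id4 was 1.75-fold higher on its brightest probe set with the other measured set in the opposite direction, and the pseudoreceptor gene Bambi was 2.74-fold lower. Without Hamp and Hamp2, the median was 1.01. Endothelial markers, from a cell type that also carries Id transcripts, had a median of 0.13 over 18 genes, with 3 higher and 2 lower by 1.5-fold or more. Among them Lyve1 was 4.71-fold higher on the brighter of its 2 probe sets and Oit3 1.57-fold higher, Clec4g was 1.98-fold lower, and Egfl7 was 1.91-fold higher with its probe sets in disagreement and a set above the floor only in the control at least 1.76-fold lower.

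Genes of iron uptake, storage, export and sensing did not stand apart as a group. Of 25 measured genes, 22 lay within 1.5-fold, 2 were higher and 1 was lower, with a median log2 ratio of 0.030 at percentile 81.4 of random lists. Scara5, a ferritin receptor, was 5.50-fold higher on 1 measured probe set (from 76.9 to 423). Slc39a14, an importer of zinc and iron, was 1.83-fold higher, with all 3 sets above the floor on both arrays in that direction, while a dim set above it only in the control was at least 1.74-fold lower. Bmp6, the BMP ligand that responds to liver iron, was 1.85-fold lower at a dim signal (45.0 and 24.3), and Neo1 (neogenin) had a ratio of -0.57 with its probe sets in disagreement and a set above the floor only in the control at least 1.92-fold lower. In control and Tmprss6-deficient liver, the transferrin receptor gene Tfrc read 311 and 286, Tfr2 read 3885 and 3283, the iron exporter gene Slc40a1 (ferroportin) read 1725 and 1512, and the ferritin heavy chain gene Fth1 read 13346 and 14916. The probe sets of Tfr2 and Slc40a1 were in disagreement.

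Heme and iron-sulfur genes were close between the animals. Heme synthesis and breakdown genes had a median of -0.057 over 12 genes, 1 higher and 1 lower by 1.5-fold or more, within the random range, and stood apart as lower with the mean of all probe sets (median -0.23, percentile 0.790). Alas2, the erythroid form of the first enzyme, was 2.56-fold lower and Cpox 1.60-fold higher, and Alad and Ppox had ratios of -0.39 and -0.37. Iron-sulfur cluster assembly genes had a median of -0.081 over 11 genes, all within 1.5-fold. Ratios were -0.52 for Lyrm4, -0.21 for Isca2, 0.46 for Hscb and 0.47 for Nfu1, the last with its probe sets in disagreement (-0.037 on the other). Hypoxia-inducible genes had a median of -0.023 over 19 genes, 15 of them within 1.5-fold, 1 higher and 3 lower. Pfkfb3, a regulator of glycolysis, was 2.43-fold lower and the kinase gene Pdk1 1.64-fold higher, while Ddit4 and Slc2a1 had ratios of 0.55 and -0.57. Erythroid markers had a median of -0.21 over 7 genes, with 0 higher and 2 lower by 1.5-fold or more. Besides Alas2, the erythroid transcription factor gene Klf1 was at least 3.23-fold lower (from 57.5 to 11.5). Hbb-b2 had a ratio of 0.53 and Tspan33 a ratio of 0.12, each with its probe sets in disagreement. Only Alas2, Hbb-b2 and Tspan33 were above the floor on both arrays, too few for a percentile. Over these, which leave out Klf1, the median was 0.12, the value of Tspan33. With the floor at the 30th percentile the list median was 0.12 as well.

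Acute-phase genes were higher in the Tmprss6-deficient liver. Of 26 measured acute-phase and IL-6-STAT3 genes, 10 were higher and 2 lower by 1.5-fold or more, and the median of 0.36 lay above all 10000 random lists. Serum amyloid A genes Saa2 and Saa1 were 4.12-fold and 3.20-fold higher, the metallothionein gene Mt2 4.57-fold (from 1030.2 to 4712) and Lcn2, which encodes the siderophore-binding lipocalin-2, 3.13-fold. Orm2 was 2.90-fold, Serpina3n 2.83-fold, Orm3 2.23-fold, Steap4 2.14-fold and Saa3 1.64-fold higher, and Stat3 was 1.80-fold higher with 1 of 4 probe sets in the opposite direction. Apcs, which encodes serum amyloid P, read 4108 and 1642, and Socs3, a feedback inhibitor of STAT3, read 108 and 52.1 with its probe sets in disagreement. Mt1 read 7713 and 7372 on the brighter of its probe sets, which were in disagreement, and the haptoglobin gene Hp read 15579.8 and 15102. Without Mt1, Mt2 and Lcn2 the median was 0.35. Neutrophil markers, which share Lcn2, had a median of -0.16 and a mean of opposite sign, 0.17, over 8 genes, with 3 higher and 1 lower by 1.5-fold or more. Csf3r was 1.83-fold and Ngp 1.58-fold higher at dim signals, and S100a8 read 60.2 and 45.1.

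Heat shock genes were also higher, with 6 of 13 higher and 1 lower by 1.5-fold or more and a median of 0.38, above all 10000 random lists. The chaperone genes Hsph1 and Hspb1 were 2.07-fold and 1.95-fold higher, each on all 2 measured probe sets, Hspa1a was 2.03-fold higher at a dim signal, and Cryab, a small heat shock protein gene, was 3.06-fold lower, while another set, above the floor only in the Tmprss6-deficient liver, was at least 1.20-fold higher. Endoplasmic reticulum stress and amino acid response genes had a median of 0.059 over 19 genes, with 2 higher and 0 lower by 1.5-fold or more. Asns (asparagine synthetase) and Chac1 were 1.87-fold and 1.72-fold higher, and Pdia4 and Herpud1 had ratios of -0.56 and -0.52. Immediate early genes differed in both directions around a median of -0.029 over 16 genes, with 2 higher and 3 lower. Egr1 read 458 and 914, Fos and Gadd45g were 2.44-fold and 2.24-fold lower, and Dusp1 had a ratio of -0.97. Cell cycle genes had a median of 0.079 over 13 genes, within the random range, with 3 higher and 1 lower by 1.5-fold or more. The list stood apart as higher with the floor at the 70th percentile (median 0.30) and with genes above the floor on both arrays only (0.36), while its median was -0.21 with the floor at the 30th percentile and -0.063 with plain probe sets only. The cell cycle inhibitor gene Cdkn1a was 4.34-fold and Rrm2 1.79-fold higher, and Mcm2 and Mcm4 had ratios of 0.43 and -0.30, the latter with its probe sets in disagreement.

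**Figure D2:**
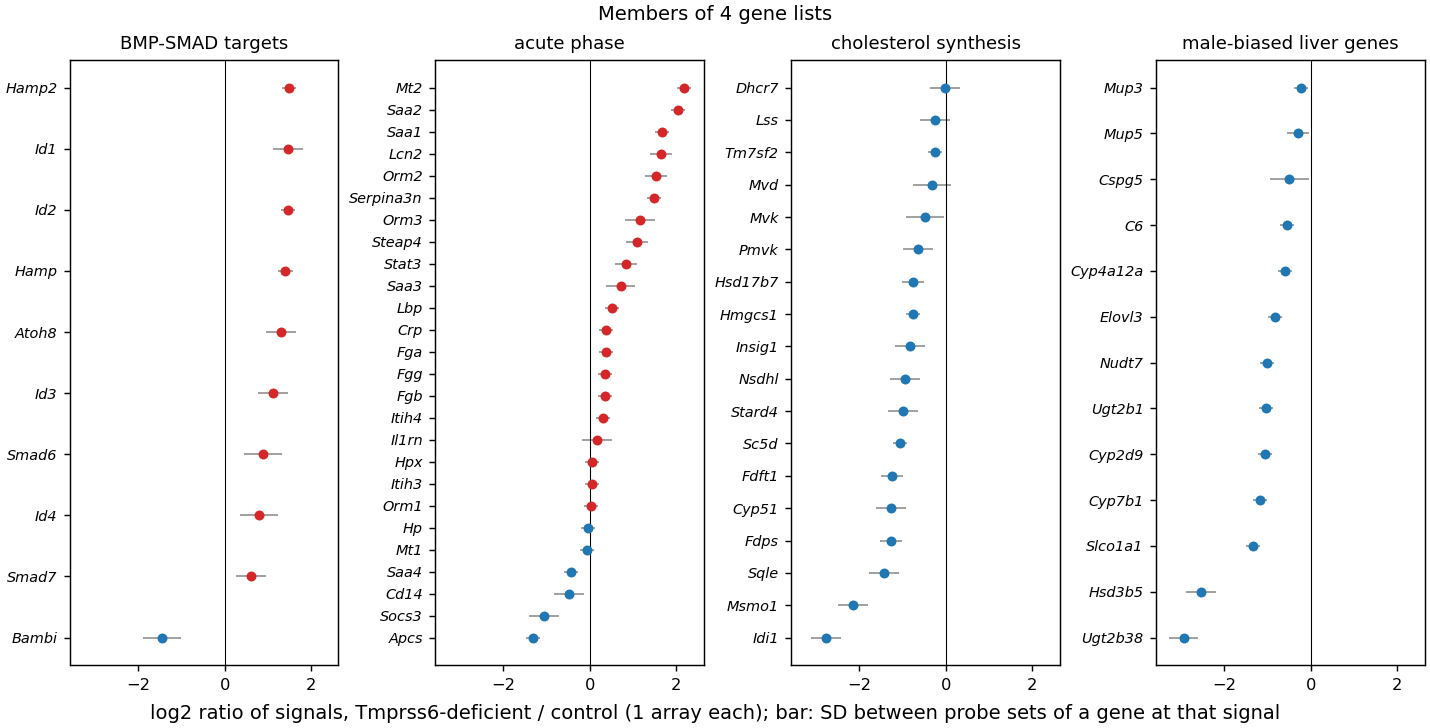
Log2 ratio (Tmprss6-deficient over control, x axis) of each measured gene in 4 gene lists, with 1 point per gene from 1 array per genotype, red where higher and blue where lower, and bars for the SD between probe sets of a gene at that signal. BMP-SMAD targets lie at a median of 1.22 with Bambi apart at -1.45, acute-phase genes at 0.36, cholesterol synthesis genes at -0.88 and male-biased genes at -1.01.

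Cholesterol synthesis genes were lower in the Tmprss6-deficient liver. Of 18 measured genes under sterol control (SREBP2), 13 were lower by 1.5-fold or more and 0 were higher, and the median of -0.88 lay below all 10000 random lists. The isoprenoid enzyme gene Idi1 was 6.83-fold lower on the brighter of its 2 probe sets, the sterol oxidase gene Msmo1 4.42-fold, the squalene epoxidase gene Sqle 2.68-fold and the farnesyl diphosphate synthase gene Fdps 2.41-fold. Without Idi1 and Msmo1 the median was -0.79. Genes of bile acid synthesis and transport had a median of -0.047 over 20 genes, within the random range, with 2 higher and 4 lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was lower on both probe sets, by 7.45-fold (1672 and 225) and by 3.10-fold. Cyp7b1 (2.26-fold), the transporter gene Slco1a1 (2.52-fold) and the nuclear receptor gene Nr0b2 (2.26-fold) were lower too, and the bile acid importer gene Slc10a2 was at least 10.9-fold higher.

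Gluconeogenesis and fasting genes were slightly lower, with a median of -0.22 over 14 genes at percentile 2.07, and 1 was higher and 3 were lower by 1.5-fold or more. The transcription factor gene Klf15 was 2.15-fold lower, Irs2 1.76-fold and G6pc (glucose-6-phosphatase) 1.59-fold, and Got1 was 1.51-fold higher. This list was within the random range with loess (percentile 5.56), with the floor at the 70th percentile (4.92) and against random lists not matched on signal (3.50). PPARA targets, genes of fatty acid oxidation that fasting induces, had a median of -0.16 over 23 genes at percentile 3.56, with 0 higher and 3 lower by 1.5-fold or more. Acot4, Acot3 and Vnn1 were 2.08-fold, 2.03-fold and 1.56-fold lower, and Fabp1 read 31166 and 23941. Fatty acid synthesis genes had a median of 0.068 over 18 genes, 2 higher and 2 lower, with the malic enzyme gene Me1 2.39-fold and Pklr 1.61-fold higher and the lipogenic regulator gene Srebf1 2.11-fold lower, and Elovl6 1.60-fold lower with its probe sets in disagreement.

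Genes with male-biased expression in mouse liver were lower in the Tmprss6-deficient male. Of 13 measured genes, 9 were lower by 1.5-fold or more and 0 were higher, and the median of -1.01 lay below all 10000 random lists. The glucuronosyltransferase gene Ugt2b38 was 7.70-fold and the steroid enzyme gene Hsd3b5 5.81-fold lower, besides Slco1a1 and Cyp7b1, without which the median was -0.82. Female-biased genes had a median of 0.38 over 6 measured genes at percentile 98.6, 3 higher and 1 lower, with Cyp17a1 2.13-fold higher, Fmo2 1.62-fold higher with its probe sets in disagreement, Cyp4a14 at 16517 and 17224 and Acot3 lower. Of the 20 genes on the female-biased list, 12 were named on the array. Among these, Cyp2b9, Cyp2b13, Cyp3a16, Sult2a2, Sult3a1 and Hao2 were below the floor on both arrays and do not enter the median. That list was within the random range with the mean of all probe sets (percentile 96.3) and with genes above the floor on both arrays only (median 0.060, percentile 71.3). Xenobiotic metabolism genes had a median of -0.084 and a mean of opposite sign, 0.030, over 18 genes, with 3 higher and 5 lower by 1.5-fold or more. The inducible cytochrome P450 gene Cyp2b10 was 7.09-fold higher on the brightest of its 3 probe sets, with the others at 6.48-fold and 5.98-fold, and Sult1d1 was 1.87-fold higher. Cyp1a2 and Aldh1a7 were 2.35-fold and 2.13-fold lower. NRF2 targets had a median of -0.093 over 14 genes, 0 higher and 4 lower, with the glutathione transferase genes Gsta4 (2.58-fold), Gsta2 (1.98-fold) and Gstm3 (1.55-fold) and the carbonyl reductase gene Cbr3 (1.79-fold) lower.

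Circadian clock genes of opposite phase differed in opposite directions. Arntl, which encodes the clock activator BMAL1, was 3.36-fold higher in the Tmprss6-deficient liver, Cry1 2.36-fold, the repressor gene Nfil3 2.27-fold and Clock 1.54-fold on the brightest of its 4 probe sets, all of them higher. With 4 measured genes this list has a median of 1.21 and no percentile. Clock genes of the Dbp and Per phase had a median of -0.47 over 12 genes at percentile 0.01, with 4 lower by 1.5-fold or more and 0 higher. Dbp, a clock output regulator, was lower on both probe sets, by 9.12-fold and 8.80-fold, and Tef was 1.71-fold lower with its probe sets in disagreement. Nr1d2 and Per1 had ratios of -0.52 and -0.51. The hour of day at which each liver was taken is not given in the sources used here.

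Interferon-inducible genes were lower in the Tmprss6-deficient liver. Of 15 measured genes, 11 were lower by 1.5-fold or more and 0 were higher, and the median of -0.65 lay below all 10000 random lists. Usp18 was 3.86-fold lower, the antiviral genes Oas1a and Rsad2 3.15-fold and 3.00-fold, the latter on the brightest of 3 probe sets, and the transcription factor gene Irf7 2.44-fold, while Ifit1 was at least 6.92-fold lower. Macrophage and Kupffer cell markers were lower as well, with a median of -0.27 over 17 genes at percentile 0.535, and with 1 higher and 4 lower by 1.5-fold or more. The complement gene C1qb was 1.89-fold lower on the brightest of its 3 probe sets, and 1.41-fold and 1.09-fold lower on the others. The Kupffer cell genes Clec4f and Vsig4 were 1.76-fold and 1.72-fold lower, and the scavenger receptor gene Marco was 1.76-fold higher. Lymphocyte markers had a median of 0.024 and a mean of opposite sign, -0.11, over 11 genes, with 1 higher and 3 lower by 1.5-fold or more. Cd52 was 2.10-fold, Ccl5 1.58-fold and Ptprc 1.56-fold lower, and Cd79a had a ratio of 0.41.

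The remaining marker lists with a percentile did not stand apart at the chosen settings. Stellate cell and fibroblast markers had a median of 0.041 and a mean of opposite sign, -0.35, over 15 genes, with 0 higher and 3 lower by 1.5-fold or more. The smooth muscle actin gene Acta2 was 5.76-fold lower on 1 measured probe set, and its plain probe set, above the floor only in the Tmprss6-deficient liver, was at least 0.20 higher on the log2 scale. The extracellular matrix genes Lum, Col1a2 and Dcn had ratios of -0.59, -0.37 and 0.38, and the plain probe set of Col1a2 was at least 0.094 higher on that scale, near the floor. Cholangiocyte markers had a median of -0.20 over 5 genes, with 0 higher and 2 lower by 1.5-fold or more. The keratin gene Krt19 was at least 2.76-fold lower (from 49.2 to 15.1) and the claudin gene Cldn7 at least 1.63-fold lower, and Anxa3 had a ratio of -0.18. The list stood apart as lower with the floor at the 30th percentile (median -0.61) and as a pseudocount (-0.96). Pancreas markers had a median of -0.18 over 6 genes, 0 higher and 2 lower, with ratios of -0.65 for Cela1, -0.12 for Cela3b and 0.46 for Prss2. Adipose markers had a median of -0.28 over 6 genes, 0 higher and 2 lower, with Lpl 1.85-fold lower. Slc2a4, Fabp4 and Pnpla2 were at -0.37, -0.18 and 0.19, with the probe sets of Fabp4 in disagreement. Muscle markers, with 4 measured genes and no percentile, had a median of -0.46, each gene above the floor on 1 array only and its bound under 1.5-fold. Genes for hepatocyte products and metabolism had a median of -0.0089 over 22 genes, with 1 higher and 0 lower by 1.5-fold or more. The albumin gene Alb read 29345 and 27850.5 and the transthyretin gene Ttr 24521 and 24403, the regulator gene Hnf4a was 1.54-fold higher on the brightest of its 4 probe sets, all of them higher, and Otc, Ass1 and Apob had ratios of -0.52, -0.32 and -0.21, with the probe sets of Otc and Apob in disagreement.

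**Figure D3:**
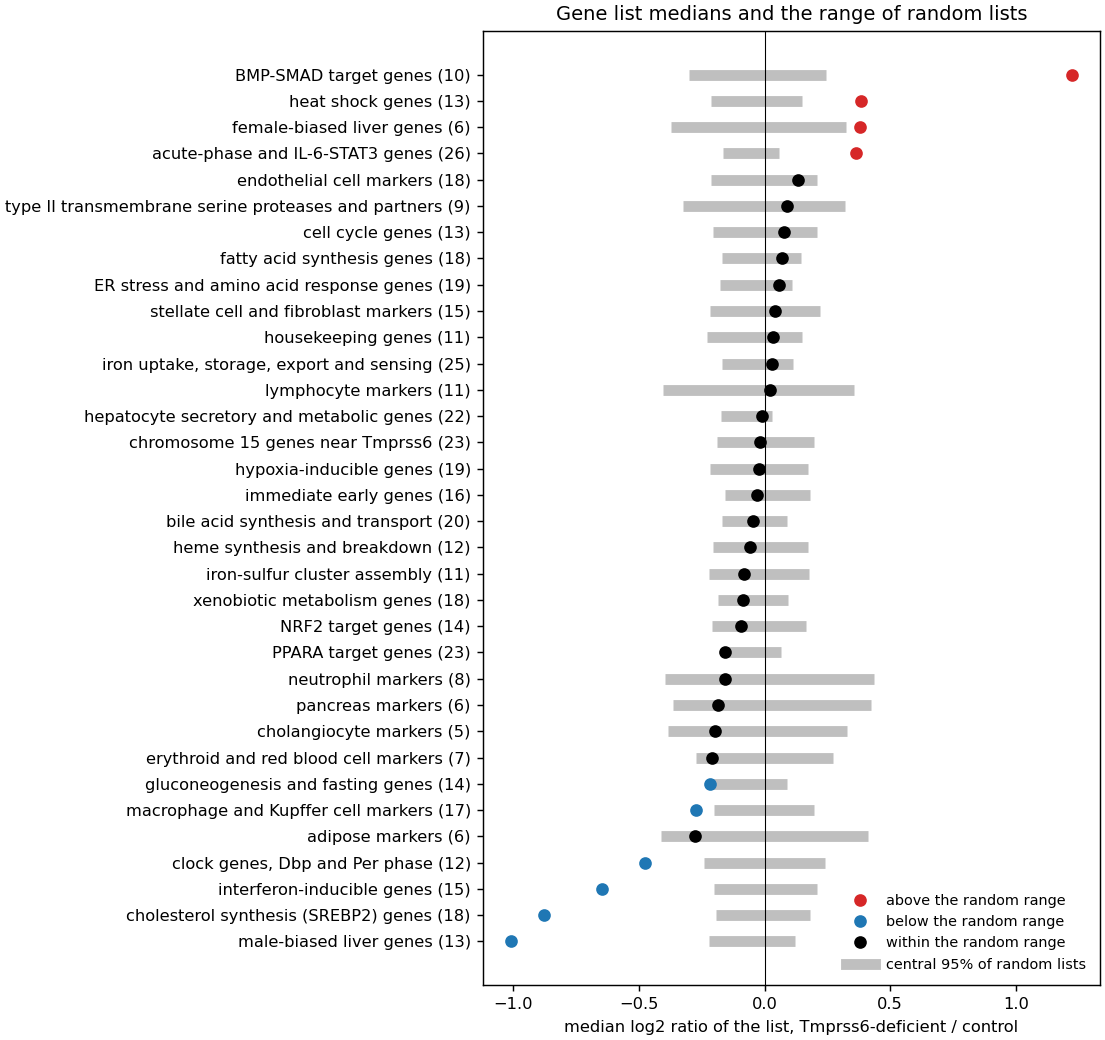
Median log2 ratio (Tmprss6-deficient over control, x axis) of each of the 34 gene lists with at least 5 measured genes, their number in brackets, with grey bars for the central 95% of 10000 random lists of like signal. The 4 red medians lie above the bars, led by BMP-SMAD targets at 1.22, and the 6 blue medians lie below, from -0.22 for gluconeogenesis genes to -1.01 for male-biased genes.

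Large differences were also seen at single named genes of diverse function, some of them list members. Among bright named genes whose measured probe sets shared a direction, Nlrp12, a NOD-like receptor gene, was 34.6-fold higher (from 33.9 to 1174). The actin-binding protein gene Cap1 was 9.75-fold higher, the securin gene Pttg1 9.13-fold, the DNA repair gene Rad51b 6.97-fold, Arrdc3 6.18-fold, the signalling regulator gene Rgs16 4.76-fold and the leptin receptor gene Lepr 4.58-fold, the last pair on 3 measured probe sets each. The dimmer set of Cap1 was 5.57-fold higher, and the control signals of its sets, 25.5 and 22.6, were near the floor. The plain probe set of Pttg1, above the floor only in the Tmprss6-deficient liver, was at least 0.48 higher on the log2 scale. The other probe set of Rad51b, above the floor only in the control, was at least 1.06-fold lower. Rbm45 was 4.47-fold, Mfsd2a 4.30-fold and Tnfrsf12a 4.30-fold higher, and E2f5 was 4.47-fold higher on 1 probe set but 1.46-fold and 1.04-fold on its others. On the lower side, Hprt, a purine salvage enzyme gene used as a housekeeping gene, was 42.4-fold lower on 1 probe set (from 1009 to 23.8). The lower signal was near the floor, and over all settings the log2 ratio of Hprt lay between -5.46 and -4.25. The cytochrome P450 gene Cyp2c39 was 26.3-fold lower, Serpina12 7.48-fold, the steroid enzyme gene Hsd17b6 6.83-fold, the chemokine gene Cxcl14 6.26-fold, the defensin gene Defb1 5.93-fold, the endothelial lipase gene Lipg 5.14-fold, Ces1g 4.76-fold and the aldehyde oxidase gene Aox3 4.64-fold. Dimmer measured sets were 3.34-fold lower for Cxcl14, 3.01-fold for Defb1 and 4.59-fold for Lipg. Of genes whose brightest probe set was above the floor in 1 animal only, Moxd1 and Dmbt1 were at least 46.4-fold and 41.4-fold lower, Rpgrip1 13.1-fold, and the smooth muscle genes Tagln and Myl9 9.91-fold and 7.10-fold. The muscle gene Myom2 was at least 33.9-fold higher, Gm7969 14.5-fold, Camk2b 6.52-fold and Mir1931 4.87-fold. Another probe set of Gm7969, above the floor on both arrays, was 7.61-fold higher.

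Housekeeping genes had a median of 0.035 and a mean of opposite sign, -0.41, over 11 genes, and a median of 0.042 without Hprt. Polr2a, Gusb and Pgk1 had ratios of 0.50, 0.33 and 0.25, the last with its probe sets in disagreement, and a dim set of Polr2a above the floor only in the control was at least 1.37-fold lower. In all, 10 of the 34 lists with a percentile stood apart, 4 higher and 6 lower. About 1.7 would do so if the lists were independent random draws of genes. Members of a list can vary together and some lists share genes, so 1.7 is not a chance rate for these lists. Control probe sets differed between the arrays. The 3 sets for 18S ribosomal RNA were 11.7 to 14.9 times brighter on the control array, and the 18 sets for the BioB, BioC, BioD and Cre spikes on the other array read 0.817 times the control signal at the median (0.708 to 1.06). The 3' to 5' signal ratio in control and Tmprss6-deficient liver was 3.33 and 2.91 for Actb, 0.934 and 0.878 for Gapdh, and 21.4 and 9.54 for Pcx.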

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

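The limits of brightness and fold used here were chosen after the data were seen, and no test was run. Probe sets with no gene name in the table used here entered no comparison. There were 9160 of them, and 3 were above the floor on both arrays, bright in the Tmprss6-deficient liver and at least 4-fold higher there than in the control. Unnamed sets lower in the Tmprss6-deficient liver, or not above the floor on both arrays, were not looked for. Probe set 1455869_at read 36.4 in the control and 5466 in the Tmprss6-deficient liver, a log2 ratio of 7.23. Probe set 1431213_a_at read 443 and 4126, a log2 ratio of 3.22. Probe set 1423867_at read 369 and 1798, a log2 ratio of 2.28. Their genes were not analysed here.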

How the results depend on the processing

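The alternatives that leave out list members were chosen after seeing the data. Under all settings that gave a value, the log2 ratio of Tmprss6 lay between -4.46 and -4.15 and that of Hamp between 1.35 and 1.51, and the BMP-SMAD, iron and acute-phase lists kept their calls, although the iron median, near 0, was -0.027 when scaled to the same median. Genes at least 2-fold higher and lower numbered 516 and 530 with the floor at the 30th percentile, 78 and 121 at the 70th, and 98 and 132 with the floor as a pseudocount. They numbered 769 and 862 at 1.5-fold and 41 and 50 at 3-fold. Under other scalings they ranged from 174 to 205 and from 251 to 285. The spread between probe sets was 0.48 with the floor at the 30th percentile, 0.28 at the 70th and 0.38 with plain probe sets only. With the mean of all probe sets, the ratios of Mcm4 (0.028), Apob (0.21), Hgf (-0.10), Hbb-b2 (-0.055), Egfl7 (-0.017) and Pgk1 (-0.11) changed sign, and with plain probe sets only, those of Acta2 (0.20), Neo1 (0.70), Otc (0.42) and Col1a2 (0.094). List medians changed sign for lymphocyte (-0.64) and neutrophil markers (0.73) with the floor at the 70th percentile, and for erythroid markers (0.12) with genes above the floor on both arrays only. Each of these settings left too few genes of the list for a percentile. Of 399 list values, 386 kept their call or, where there was no percentile, their sign, 5 lost a call, 5 gained one and the 3 above were reversed. Of the 386, 28 also changed sign, among them cell cycle genes (-0.21) and neutrophil markers (0.29) with the floor at the 30th percentile. The 13 lists whose median changed sign in any alternative were all within the random range at the chosen settings, so their medians have no settled direction. Of 1405 values of named genes, 1308 differed by at most the probe set spread, 87 by more and 10 were reversed. Of the 87, 52 are bounds, or averages that include one, which leave the size of the ratio open, and a further 17 come from the pseudocount, which draws ratios of dim genes towards 0. Of the 10, Acta2 and Col1a2 are bounds and the averages of Hgf and Egfl7 include one. Different probe sets represent the gene in those 10, and floors and thresholds admit more or fewer genes, and the cause was not tested otherwise. No paired analysis was possible because each group has 1 array, and no array could be left out. Signal over background limits what can be said of genes near the floor.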

Other observations

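Tests on the genes with differences over 16-fold and on hepcidin were chosen after their results were seen, and those on contractile and epithelial genes were written before, although the bootstrap interval used to read them was added after their values were seen.

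Genes of contractile smooth muscle were lower in the Tmprss6-deficient liver beyond those named so far. Actg2, the enteric smooth muscle actin gene, was at least 4.70-fold lower and the tropomyosin gene Tpm2 3.33-fold lower, and with Acta2, Tagln and Myl9 they prompted a check of other contractile genes. Of 12 such genes, 4 were lower by 1.5-fold or more and 0 were higher, and the median of -0.43 lay at percentile 0.120 of random lists. The smooth muscle myosin gene Myh11 was at least 3.97-fold and the calponin gene Cnn1 at least 3.55-fold lower, Csrp1 was 2.36-fold and the filamin gene Flna 2.12-fold lower, and Cald1 read 3832 and 3949. Epithelial genes of ducts and gallbladder had a median of -0.26 over 12 genes at percentile 3.85, with 5 lower by 1.5-fold or more. Cd24a was 2.83-fold and Krt23 2.55-fold lower, Ly6d was at least 3.24-fold lower, and Lgals4 and Krt18 read 66.7 and 96.3 and 1985 and 1931. Of the duct markers fixed before, Krt19 was at least 2.76-fold and Cldn7 at least 1.63-fold lower.

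A candidate explanation for the contractile genes is that the piece of control liver held more vessel or duct wall, or some gallbladder. Before their values were seen, a median of -0.6 or lower was set as speaking for each, and a median above -0.3 as speaking against. The contractile median of -0.43 fell between these bounds, with a 95% bootstrap interval from -1.16 to -0.14. The epithelial median of -0.26 passed the bound against gallbladder, but its interval from -1.39 to -0.031 reached below -0.6, and with that interval, which was added after the value was seen, the test no longer counts as excluding it. So neither tissue source can be told apart from the genotype for these genes.

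Hprt, Cyp2c39, Moxd1, Dmbt1, Nlrp12 and Myom2 differed by over 16-fold, as Tmprss6 did. Their 56 measured neighbours had a median log2 ratio of 0.024, signed in the direction of their gene. Pooled over unlinked places, that median cannot speak for a single gene. Gene by gene, it ran from -0.39 for Myom2 (11 neighbours) to 0.20 for Dmbt1 (12), and was 0.053 for Hprt over only 5. These medians argue against a change of the whole chromosome neighbourhood at each gene, but not against a change limited to the gene itself. The 6 genes go both ways, and at most 0.6% of the 500 genes nearest in signal to each differed 4-fold or more in its direction. The differences were thus not shared by genes of like signal. Since the arrays were scaled alike and 84.1% of genes lay within 1.5-fold, that share could hardly have been high. It therefore does not decide on an array-wide difference in RNA amount, labelling or scaling. RNA handling that affects single transcripts was not tested, and the 18S sets and the 3' to 5' ratio of Pcx did differ. An inherited allele of the gene itself, from the mixed 129Sv and C57BL6 background or from the targeted stem cells, stays open beside loss of Tmprss6, and some stem cell lines used for gene targeting lack Hprt. With 1 animal per genotype the inherited allele and the loss of Tmprss6 cannot be told apart. The tissue sources considered above for the contractile genes were not tested for these 6 genes and stay open too.

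Hepcidin and the BMP-SMAD targets were higher together with acute-phase genes, and IL-6 acting through STAT3 also raises hepcidin. The BMP-SMAD targets other than Hamp and Hamp2 had a median of 1.01, but they are part of the pattern itself, so this value does not test whether that response is the cause, which stays open. Endothelial markers had a median of 0.13, with a 95% bootstrap interval from -0.20 to 0.37, below the 1.01 of these targets. That argues against a larger share of endothelial cells as the whole of the difference. The interval covers the spread among markers on these 2 arrays and not the variation between animals. An inflammatory signal that acts through SMAD factors stays open, as does a difference between these 2 animals unrelated to genotype, and neither was tested.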
